A study of Arabidopsis thaliana with 6 samples.

How the data were processed

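Messenger RNA was measured by RNA sequencing in leaves of Arabidopsis thaliana of the Col-0 accession, in 3 wild-type samples and in 3 samples titled as transgenic lines 1 to 3. Per the labels' protocols, leaves were taken from 4-week-old plants, total RNA was extracted and treated with DNase, polyadenylated RNA was selected on oligo(dT) beads, cDNA was primed with random hexamers, and the libraries were read on a HiSeq 2000. The labels do not name the transgene. The protocol mentions drought treatments in identical words for all 6 samples, so watering cannot be told apart between the groups from the labels. Nothing in the labels says that the wild-type replicates came from separate plants or pools, so p-values measure the spread between these samples, which may be technical.

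The deposited values are labelled FPKM, by definition fragment counts scaled for transcript length and for library size, made by the authors and given as 1 table with 1 column per sample. Per the submitters' processing notes, TopHat2, DESeq and the TAIR10 build were used, with no version and no role for each. The program that produced the FPKM, the annotation, the fragment type and whether strand was used are not given in the sources used here. The deposited table lists 21981 genes, of which 21548 were matched by locus to the TAIR10.1 annotation, used here for symbols, products, coordinates, exonic lengths and GC content. The others are 286 gene models added by the authors, 32 chloroplast loci, 61 mitochondrial loci and 54 other loci. All 6 sample columns were used, and 561 genes were at 0 in every sample.

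FPKM times exonic length in kilobases would sum to the same total in every sample if each were scaled to its own assigned fragments. These sums were 1383780 to 1407487 in wild type and 1782237 to 1810068 in the transgenic lines, on the reference lengths. What the authors divided by is therefore unknown, its ratio to the assigned fragments differs between the groups, and fold changes on the values as deposited carry that difference.

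FPKM do not give the number of reads, so the absolute depth is unknown. Low values fall on steps, each the worth of 1 read, and comparing these steps between samples gave the number divided by, relative to wild-type replicate 1: 0.99 and 1.59 for wild-type replicates 2 and 3, and 0.78, 0.98 and 0.70 for transgenic lines 1, 2 and 3. Together with the sums above, this puts assigned fragments relative to wild-type replicate 1 at 0.98 and 1.56 for the other wild-type replicates and at 1.0, 1.24 and 0.90 for the lines. Of the 15 pairs of samples, 13 were within 0.05 of these ratios on the log2 scale. The others both hold wild-type replicate 3, whose values are therefore less sure. Their most common log2 ratios were -0.32 (wild-type replicate 2 over replicate 3) and 0.29 (wild-type replicate 3 over line 2). Only 1.95% to 11.13% of the low genes of a pair lay close to its most common ratio. No whole read counts were recovered from the FPKM, so no count test was run. Without counts, no counting interval or detection floor can be given, and precision rests on the spread among the 3 samples of each group. Reads shared by near-identical genes could be split in ways that the sources used here do not give. This concerns, among others, LHCB1.1, LHCB2.1, AOC1, AOC2, IGMT3 and NIT2, each of which has close paralogs. Of the 99 named genes with coordinates, 18 overlap another annotated gene, among them GL2, SPL9, MYB106, KRP4, RCA, LUX and ELF3, and their values may hold reads of that neighbour.

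The comparison was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the values as deposited, with all 6 samples, no covariate and a mean-variance trend. Genes with a mean of at least 1 FPKM over the 6 samples were tested, 17093 in all, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are transgenic over wild type on the log2(FPKM + 1) scale, which understates the change of genes with low values. Standard errors (SE) are limma's moderated errors, and means are given with the SD over 3 samples. The numbers in the titles name a wild-type replicate or a transgenic line, and the labels do not say that they pair samples.

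Before the data were examined, 24 lists with 438 loci were fixed, for trichomes, the endocycle, mitosis, DNA replication, stress and hormone responses, metabolism and tissue markers. Of these loci, 426 were in the table. The symbols of 421 matched the reference, 17 were kept without a match and 0 were dropped. Lists with at least 3 tested members were tested with limma's camera, a competitive test against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way and compares it with no other gene, were run beside it. A count "adjusted over the list alone" uses adjustment over the tested members of that list.

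Genes are named by a rule also fixed then: the 10 higher and 10 lower genes with the largest absolute fold change among called genes whose groups do not overlap, then up to 4 called members of each list by smallest p, with at least 3 members by smallest p for the 6 lists on trichomes, endocycle, mitosis and replication. Examples below come from this set unless they are said to be chosen after their values were seen. In all named genes but TCL2, the 3 transgenic values lay on one side of the 3 wild-type values.

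The fit was tested on simulated data for this comparison, with 16904 genes at their observed levels and spread. It recovered 48.5% of 68 genes changed by 0.5 on the log2 scale, 92.4% of 66 changed by 1 and 100% of 66 changed by 2, and 6.4% of 171 calls were false. With no change simulated, 1 gene was called. A shifted list, that of photosynthesis, was called, with 0 of 21 other lists. Genes were simulated independently of each other, so list calls among correlated members were not tested. The genes given a change had a wild-type mean of at least 2 FPKM, so recovery of genes with smaller values was not tested either. They were a far smaller share of all genes than the 40.7% called in the real comparison, and the adjusted threshold depends on that share. The simulated groups had no difference in scaling and no trend of fold changes with level. The recovered and false shares therefore do not carry over to the real comparison.

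The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, median-of-ratios size factors, quantile normalization, rescaling to TPM, limma without a trend, array weights, the title number as a block, a minimum 2-fold change, each sample left out in turn, and the other list tests. Cyclic loess normalization and a minimum exonic length of 500 bases were chosen after seeing the data. Matched random lists, permutation tests and plots used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.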

Results

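Leaf transcriptomes of wild-type Arabidopsis and of 3 transgenic lines were compared, 3 samples against 3. The series title places the comparison in the study of endoreplication, the copying of nuclear DNA without cell division, and of the branching of trichomes, the single-celled hairs of the leaf surface. Summed FPKM were 976844, 970376 and 982620 in the wild-type samples and 1278449, 1261802 and 1272266 in the transgenic lines. In a principal component analysis of log2 values, component 1 held 66.4% of the variance and separated the groups, and component 2 held 10.3%. Pearson's r across genes was 0.985 to 0.987 between wild-type samples, 0.983 to 0.984 between transgenic lines and 0.950 to 0.955 between groups, where genes are not independent replicates. The median absolute difference of a gene between samples was 0.30 to 0.32 on the log2 scale between groups and at most 0.14 within a group.

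NCED3, the key enzyme of abscisic acid synthesis, rose from 6.78 ± 0.39 FPKM in wild type to 71.7 ± 1.68 FPKM in the transgenic lines (SD, n = 3), a log2 fold change of 3.23 (SE 0.075, limma adjusted p = 2.54e-08). PR1, a marker of salicylic acid defence, fell from 37.0 ± 1.79 to 1.95 ± 1.12 FPKM, and GL2, a homeodomain regulator of trichome development, fell from 4.06 ± 0.283 to 0.679 ± 0.21 FPKM. Among gene lists fixed before the data were examined, 25 of 26 photosynthesis genes, 18 of 24 jasmonate genes, 12 of 22 drought genes and 8 of 10 cold genes rose in the transgenic lines. In the other direction, 15 of 23 mitotic genes, 16 of 41 endocycle regulators and 8 of 11 early auxin response genes fell. These counts are for the values as deposited, and scaling moved some of them. Photosynthesis had 7 higher and 4 lower after quantile normalization, and the drought list 7 and 7 after rescaling to TPM. The jasmonate list kept 17 higher and 3 lower after quantile normalization and 16 and 3 after TPM. Of 17093 genes tested with limma, 6949 (40.7%) changed, 4273 of them higher and 2676 lower in the transgenic lines.

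The size of most changes was moderate, with a median absolute log2 fold change of 0.58 among called genes. At least 2-fold changes numbered 1278, with 717 higher and 561 lower, and at least 4-fold changes 107, with 40 higher and 67 lower. The 3 transgenic values lay all above or all below the 3 wild-type values in 8923 genes, 52.2% of those tested, where chance gives 10%. The balance of directions depended on scaling. The share of higher calls was 61.5% with the values as deposited. It was 48.9% (3284 higher, 3434 lower) after quantile normalization and 49.2% (3290 higher, 3396 lower) after cyclic loess, chosen after seeing the data. It was 18.6% (1907 higher, 8363 lower) after rescaling to TPM, a step that moved the median of all genes from 0.03 to -0.31. None of the named genes turned direction under these scalings.

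**Figure D1:**
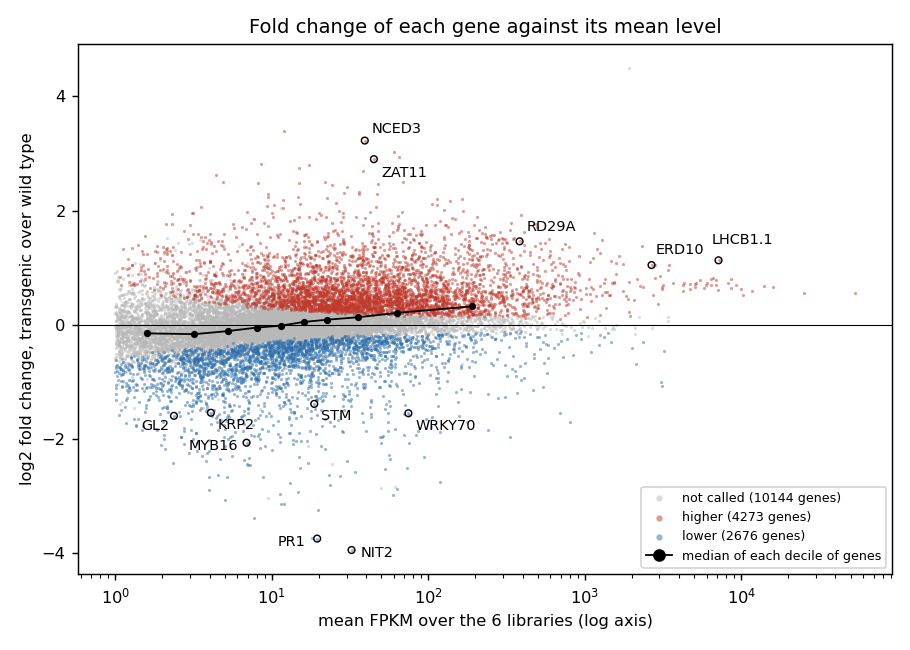
Log2 fold change of each tested gene (transgenic over wild type, vertical axis) against its mean FPKM over the 6 libraries (horizontal log axis), with the 4273 genes called higher in red, the 2676 called lower in blue and the others in grey; circles mark named genes and the black line joins the medians of expression deciles. These medians run from -0.15 in the lowest decile to 0.32 in the highest.

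Beside NCED3, the 10 genes with the largest rises included the protein phosphatase 2C gene AT1G07160 (log2 fold change 3.39, SE 0.122), the zinc finger gene ZAT11 (2.90, SE 0.103) and the transcription factor genes TDR1 (2.94, SE 0.124) and WRKY30 (2.80, SE 0.097). IGMT3, a methyltransferase gene of indole glucosinolates, rose by 2.69 (SE 0.115). WRKY30 went from 3.58 ± 0.314 to 31.0 ± 1.17 FPKM. The rest of that set were AT1G05675, AT1G71520, AT5G11140 and 1 gene model added by the authors, with log2 fold changes from 2.63 to 3.03. The largest fall was that of the nitrilase gene NIT2, from 61.6 ± 3.84 to 3.05 ± 0.139 FPKM (log2 fold change -3.95, SE 0.088, adjusted p = 2.54e-08). PR1 fell by 3.75 on the log2 scale (SE 0.221). The auxin-responsive gene AT4G38860 had a log2 fold change of -3.39 (SE 0.252) and the trypsin inhibitor gene KTI1 one of -3.24 (SE 0.166). Those of the actin-depolymerizing factor gene ADF9 and the osmotin-like gene OSM34 were -3.15 (SE 0.265) and -3.15 (SE 0.161). AT1G49230, AT5G61590, CCOAMT and AT3G10190 completed the set, with log2 fold changes from -3.07 to -2.94. On TAIR10.1, NCED3 (AT3G14440) lies on chromosome 3 at 4831286 to 4834015 and GL2 (AT1G79840) on chromosome 1 at 30036956 to 30041440. Each value covers a whole annotated gene.

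Of 20 activators of trichome initiation, 19 were in the table and 8 reached the mean of 1 FPKM needed for testing. GL1 and GL3 were among those below it. Among the 8 tested members 3 fell and 0 rose, the same count when adjusted over the list alone. With no filter 19 were tested, 5 were lower and 0 higher (camera adjusted p = 0.00606), where the added members had means under 1 FPKM. After quantile normalization 3 were lower, and after rescaling to TPM 7. GL2 fell by 1.6 on the log2 scale (SE 0.176, limma adjusted p = 8.88e-05), the zinc finger gene ZFP8 fell from 20.3 ± 2.73 to 6.36 ± 1.3 FPKM, and the bHLH gene MYC1 fell from 3.68 ± 0.733 to 1.42 ± 0.432 FPKM. The list's median log2 fold change was -0.48 with a camera adjusted p of 0.0456. The adjusted p was 0.232 with an estimated correlation, and the call was also lost without wild-type replicate 1 (adjusted p = 0.0626) and without wild-type replicate 2 (0.0534). Over its 20 alternatives, left-out samples and other list tests included, the adjusted p ran from 0.00183 to 0.362, and the call ended under each of the 4 other scalings. Of 8 tested genes listed as trichome repressors, 2 fell, SPL3 (log2 fold change -0.40, SE 0.069) and SPL9 (-0.84, SE 0.16), and 0 rose, again the same count adjusted over the list alone. TCL2, a small MYB repressor, had values of 33.2, 27.8 and 32.3 FPKM in wild type and 31.5, 10.1 and 14.4 FPKM in transgenic lines 1, 2 and 3. It missed the threshold (adjusted p = 0.0616) but passed it without line 1 (log2 fold change -1.29, adjusted p = 0.000261; range over its alternatives 0.000261 to 0.165). TCL2 also passed under some other settings, among them TPM (limma adjusted p = 0.00858), the title number as a block (0.0177) and quantile normalization (0.0386). The repressor list was not called (camera adjusted p = 0.147).

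Of 23 genes of trichome branching and cell shape, 2 were higher, 4 lower and 17 not called with the values as deposited (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.205). The counts were 2 higher and 7 lower after quantile normalization and after cyclic loess, and 0 higher and 16 lower after rescaling to TPM. The MIXTA-like genes MYB16 and MYB106, the second a repressor of branching, fell from 11.7 ± 1.11 to 2.05 ± 0.437 FPKM and from 2.98 ± 0.915 to 0.949 ± 0.432 FPKM. TBR, needed for crystalline cellulose in trichomes, rose from 46.0 ± 3.46 to 66.3 ± 4.33 FPKM, a call that ended after rescaling to TPM (adjusted p = 0.128; range over its alternatives 0.000349 to 0.128). ARP3, an actin-nucleating subunit, rose by 0.44 on the log2 scale (adjusted p = 0.0308) and lost its call without wild-type replicate 1 or 2 and without line 1 or 2. The ARP3 call also ended after TPM (log2 fold change 0.105, limma adjusted p = 0.52), with median-of-ratios factors (0.0528) and with no filter (0.0564). Its range over the alternatives was 0.0138 to 0.52.

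Endocycle regulators fell more often than they rose, with 16 of 41 lower, 2 higher and the same counts adjusted over the list alone. GTL1, which ends growth and endoreplication in trichomes, fell from 32.5 ± 0.778 to 15.5 ± 0.577 FPKM. The cyclin-dependent kinase inhibitor genes KRP2 and KRP4 fell from 6.55 ± 0.232 to 1.6 ± 0.232 FPKM and from 15.3 ± 2.09 to 5.90 ± 0.462 FPKM, and the transcription factor gene TCP15 fell by 0.93 on the log2 scale (SE 0.093, limma adjusted p = 4.65e-05). TCP15 is known as a repressor of endoreplication. Promoters of endoreplication fell as well: SIM and LGO, chosen after their values were seen, had log2 fold changes of -0.50 (SE 0.137) and -1.30 (SE 0.156). The list thus holds genes that act both ways, and its fall gives no direction for endoreplication itself. The list's median was -0.21 (camera adjusted p = 0.00096; adjusted p = 0.0875 with an estimated correlation). Its median was -0.066 with an adjusted p of 0.0518 after quantile normalization, and the adjusted p over its alternatives ran from 0.000157 to 0.0875.

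Mitotic genes were lower in 15 of 23 tested members and higher in 0, and lower in 16 when adjusted over the list alone. After quantile normalization 11 were lower, and after rescaling to TPM 22. The cyclin gene CYCA1;1 fell from 3.52 ± 0.131 to 0.880 ± 0.123 FPKM and CYCB2;3 from 5.00 ± 0.364 to 2.0 ± 0.372 FPKM. The mitotic kinase genes CDKB2;1 and CDKB2;2 fell from 12.5 ± 1.04 to 7.13 ± 0.596 FPKM and from 10.9 ± 1.26 to 5.97 ± 0.276 FPKM. The list's median log2 fold change was -0.57 (camera adjusted p = 2.44e-06; adjusted p = 0.0875 with an estimated correlation). DNA replication genes had 4 of 19 members lower, 0 higher and, with limma, 0 called adjusted over the list alone (7 at an unadjusted p under 0.05), with a median of -0.27 (camera adjusted p = 0.0245; adjusted p = 0.194 with an estimated correlation; 0.00494 to 0.313 over its alternatives). PCNA2, the sliding clamp gene, fell from 21.8 ± 3.29 to 16.4 ± 0.685 FPKM and lost its call without wild-type replicate 1 or without line 3. The S-phase cyclin genes CYCA3;1 and CYCA3;2 and the helicase subunit gene MCM5 fell with adjusted p from 0.0196 to 0.0445, and each lost its call without at least 3 of the samples in turn. In this list 2 members were lower after quantile normalization and 11 after rescaling to TPM. The replication list's median lay at percentile 5.32 of 10000 random lists matched on mean expression. It was inside their central range, -0.3 to 0.103, so this fall is not told apart from the trend of fold changes with expression level.

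STM, which maintains the shoot meristem, fell from 27.5 ± 1.26 to 9.87 ± 0.322 FPKM (log2 fold change -1.39, SE 0.082, limma adjusted p = 1.5e-06), and its relatives KNAT1 and KNAT2 fell from 9.83 ± 0.654 to 4.8 ± 1.31 FPKM and from 2.89 ± 0.076 to 0.770 ± 0.361 FPKM. The flowering gene FUL fell from 7.87 ± 0.839 to 4.63 ± 0.228 FPKM. Of 13 tested meristem and floral markers, 5 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0145; adjusted p = 0.165 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.134; range over its alternatives 0.00112 to 0.176). It also ended after rescaling to TPM (camera adjusted p = 0.176), after cyclic loess (0.123) and at a mean of at least 5 FPKM (0.0627). In the stomatal lineage list 4 of 10 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.147), with 2 lower and 1 higher after quantile normalization and 7 and 0 after rescaling to TPM. SPCH, which starts that lineage, fell from 2.28 ± 0.373 to 0.358 ± 0.193 FPKM. TMM fell from 5.50 ± 1.33 to 2.85 ± 0.621 FPKM and lost its call without wild-type replicate 1 or 2. EPF2 and GORK were the other 2, with adjusted p of 0.0453 and 0.0458, and both lost the call without most of the samples in turn.

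**Figure D2:**
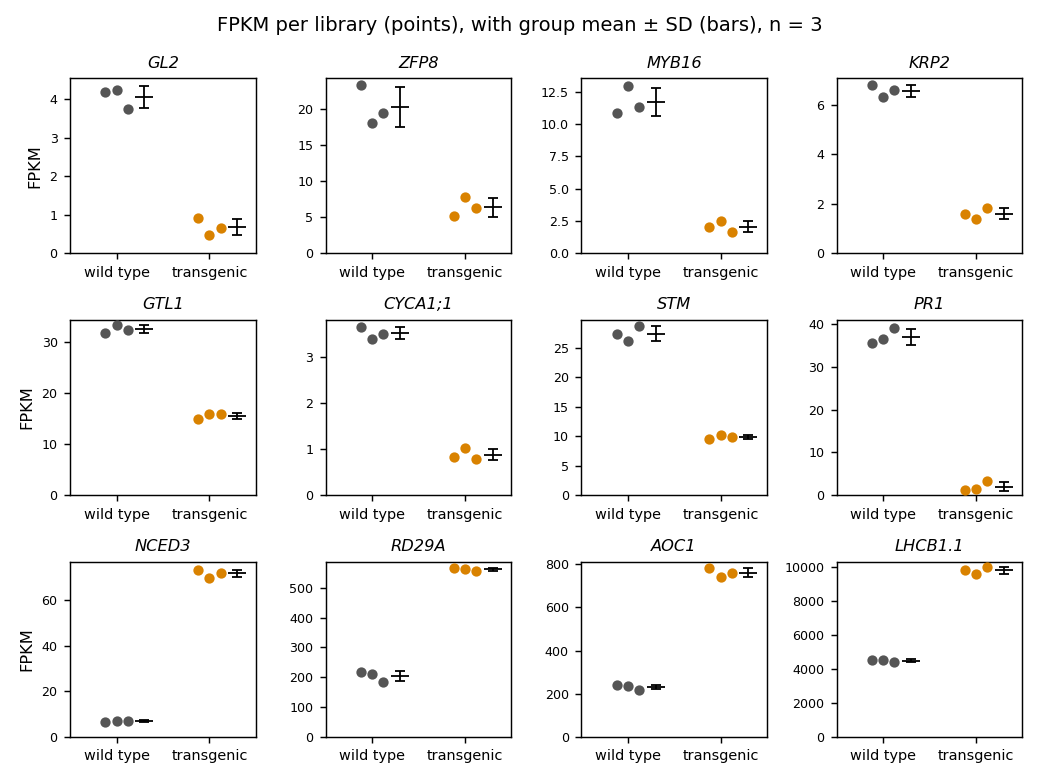
FPKM (vertical axes, from 0) of 12 named genes in the 3 wild-type and 3 transgenic libraries, each point 1 library, with the group mean and SD as a bar beside the points. The groups do not overlap in any of the 12 genes, with GL2, ZFP8, MYB16, KRP2, GTL1, CYCA1;1, STM and PR1 lower and NCED3, RD29A, AOC1 and LHCB1.1 higher in the transgenic lines.

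Genes of abscisic acid and drought response were higher in 12 of 22 tested members and lower in 3 (13 higher and 4 lower adjusted over the list alone). Beside NCED3, the dehydrin gene ERD10 rose from 1742 ± 31.1 to 3595 ± 36.7 FPKM and the stress-inducible gene RD29A from 204.1 ± 17.3 to 561.8 ± 5.09 FPKM. P5CS1, of proline synthesis, rose from 62.8 ± 3.36 to 129.9 ± 5.28 FPKM. The list's median was 0.40 (camera adjusted p = 0.0145; adjusted p = 0.165 with an estimated correlation), and after rescaling to TPM 7 members were higher and 7 lower. Of 10 cold response genes, 8 were higher and 1 lower (9 and 1 adjusted over the list alone). COR15A was at 300.0 ± 20.9 and 629.4 ± 11.3 FPKM and GOLS3, a galactinol synthase gene, at 1.83 ± 0.647 and 14.5 ± 0.756 FPKM in wild type and transgenic lines. The cold list's median was 0.66 (camera adjusted p = 0.000423; adjusted p = 0.232 with an estimated correlation) and 0.28 after quantile normalization. Heat shock genes were lower in 3 of 8 and higher in 0, also adjusted over the list alone, among them HSP70, which fell from 6.0 ± 0.125 to 3.17 ± 0.122 FPKM. The heat shock list's median of -0.37 lay at percentile 8.28 of 10000 random lists matched on mean expression. It was inside their central range, -0.485 to 0.212, so this fall is not told apart from the trend of fold changes with expression level. The list's camera test gave an adjusted p of 0.0472 (adjusted p = 0.194 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.285) and without wild-type replicate 1 or 2 or line 2 or 3, with a range of 0.00127 to 0.287 over its alternatives.

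Jasmonate genes were higher in 18 of 24 tested members and lower in 2 (19 and 2 adjusted over the list alone). The jasmonate synthesis genes AOC1, AOC2 and LOX3 rose from 230.6 ± 10.8 to 760.9 ± 21.2 FPKM, from 443.8 ± 16.5 to 1142 ± 44.1 FPKM and from 305.2 ± 14.7 to 867.8 ± 8.07 FPKM. JAZ1, a repressor of jasmonate signalling, rose by 1.18 on the log2 scale (SE 0.035, limma adjusted p = 4.33e-08). The list's median was 0.99 (camera adjusted p = 6.31e-09; adjusted p = 0.0875 with an estimated correlation). The salicylate list was split, with 9 of 18 higher and 7 lower (10 and 7 adjusted over the list alone), a median of 0.41, a mean of -0.03 and a camera adjusted p of 0.732. After rescaling to TPM 7 of them were higher and 8 lower. EDS1 and CBP60G, regulators of this defence, rose from 23.0 ± 0.727 to 52.5 ± 1.00 FPKM and from 51.6 ± 1.66 to 141.5 ± 3.51 FPKM. PR1 and WRKY70 fell, the latter from 111.7 ± 5.88 to 37.5 ± 2.43 FPKM. Of 16 leaf senescence genes, 8 were higher and 4 lower, also adjusted over the list alone (median 0.38, camera adjusted p = 0.2). After quantile normalization 6 were higher and 4 lower (median 0.21), and after rescaling to TPM 4 and 5 (median 0.004). WRKY53 rose from 37.1 ± 0.474 to 122.2 ± 6.86 FPKM and SAG21 from 555.2 ± 23.4 to 1283 ± 45.1 FPKM.

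Early auxin response genes were lower in 8 of 11 tested members and higher in 1, also adjusted over the list alone. The auxin-inducible genes IAA4 and GH3.6 fell from 30.9 ± 0.666 to 7.5 ± 0.546 FPKM and from 27.9 ± 1.37 to 6.96 ± 0.68 FPKM, while IAA19 rose from 19.0 ± 2.5 to 33.5 ± 1.11 FPKM. The list's median was -0.44 (camera adjusted p = 0.00248; adjusted p = 0.133 with an estimated correlation), with an adjusted p of 0.0635 after rescaling to TPM (range over its alternatives 0.000339 to 0.133). Among gibberellin genes 7 of 14 were higher and 4 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.44), with 5 higher and 6 lower after rescaling to TPM. GA2OX6 and GA2OX2, which inactivate gibberellins, rose from 58.7 ± 2.73 to 198.4 ± 9.82 FPKM and from 22.5 ± 1.15 to 47.4 ± 5.21 FPKM. Of the gibberellin-regulated genes, GASA4 fell from 338.8 ± 29.1 to 144.3 ± 7.32 FPKM and GASA6 rose from 119.5 ± 12.1 to 231.4 ± 9.26 FPKM.

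Of 22 glucosinolate genes, 10 were higher and 9 lower with the values as deposited, also adjusted over the list alone (median -0.03, camera adjusted p = 0.751). The counts were 7 higher and 10 lower after quantile normalization (median -0.16) and 6 and 13 after rescaling to TPM (median -0.36). MAM1, of methionine chain elongation, fell from 255.1 ± 5.58 to 111.8 ± 2.39 FPKM. MYB34 and CYP83B1, of the indole branch, rose from 22.4 ± 0.3 to 52.2 ± 2.51 FPKM and from 310.8 ± 10.7 to 538.6 ± 3.33 FPKM. Cuticular wax genes were lower in 6 of 11 and higher in 2, also adjusted over the list alone (camera adjusted p = 0.0517). The list passed without line 1, 2 or 3 (adjusted p = 0.0281, 0.0283 and 0.0199; range over its alternatives 0.00494 to 0.232). It also passed with no filter (camera adjusted p = 0.00606), cyclic loess (0.0477) and array weights (0.0499), and with fry. It did not pass after quantile normalization (camera adjusted p = 0.0518) or TPM (0.152). CER6 and CER1, of wax synthesis, fell from 163.8 ± 2.08 to 105.3 ± 1.84 FPKM and from 14.1 ± 1.22 to 6.87 ± 0.886 FPKM. KCS1, also of wax synthesis, and the wax regulator MYB96 rose from 72.7 ± 2.61 to 105.1 ± 1.29 FPKM and from 41.0 ± 1.84 to 68.1 ± 4.07 FPKM. In flavonoid synthesis 1 of 8 was higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.63), with 4 higher after quantile normalization and 0 after rescaling to TPM. The anthocyanin regulator PAP1 fell from 6.31 ± 0.409 to 2.39 ± 0.807 FPKM. F3H rose from 2.95 ± 0.5 to 5.19 ± 1.13 FPKM, a call lost without wild-type replicate 2, without line 1 and after rescaling to TPM.

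Photosynthesis genes were higher in 25 of 26 tested members and lower in 0, also adjusted over the list alone. LHCB1.1, a light-harvesting protein gene of photosystem II, rose from 4490 ± 64.3 to 9815 ± 199 FPKM (log2 fold change 1.13, SE 0.031, limma adjusted p = 3.62e-08), LHCB2.1 rose by 1.05 on the log2 scale (SE 0.032), and RCA, which activates the carbon-fixing enzyme Rubisco, rose from 2154 ± 81.0 to 3896 ± 49.8 FPKM. The list took 15.8%, 15.8% and 14.9% of the FPKM total in the wild-type samples and 19.0%, 18.7% and 19.1% in the transgenic lines. Its median was 0.69 (camera adjusted p = 1.12e-16; adjusted p = 0.13 with an estimated correlation). After quantile normalization 7 members were higher and 4 lower, with a median of 0.05 and an adjusted p of 0.188, so that the call ended (range over its alternatives 4.73e-22 to 0.188). After rescaling to TPM 25 were higher and 1 lower with a median of 0.31. Fold changes rose with expression level across all genes (Spearman's rho 0.34 across 17093 genes, which are not independent replicates), and this list holds some of the most abundant transcripts of the leaf.

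Of 16 circadian clock genes, 6 were higher and 6 lower with the values as deposited (6 and 7 adjusted over the list alone; camera adjusted p = 0.147). The counts were 5 higher and 9 lower after quantile normalization and after cyclic loess, and 2 higher and 11 lower after rescaling to TPM. The evening complex genes ELF4, LUX and ELF3 fell from 36.2 ± 3.66 to 10.5 ± 2.19 FPKM, from 45.9 ± 1.6 to 21.7 ± 2.44 FPKM and from 19.4 ± 0.526 to 9.62 ± 0.574 FPKM. The clock-controlled gene GRP7 fell from 4075 ± 455 to 2021 ± 80.1 FPKM. Vascular markers had 2 of 8 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.933). The phloem sucrose transporter gene SUC2 rose from 68.7 ± 1.36 to 117.1 ± 2.86 FPKM and SWEET12 fell from 35.7 ± 0.641 to 19.9 ± 1.85 FPKM. Of the 4 root hair and 4 seed storage markers, all in the table, 0 reached the mean of 1 FPKM needed for testing.

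**Figure D3:**
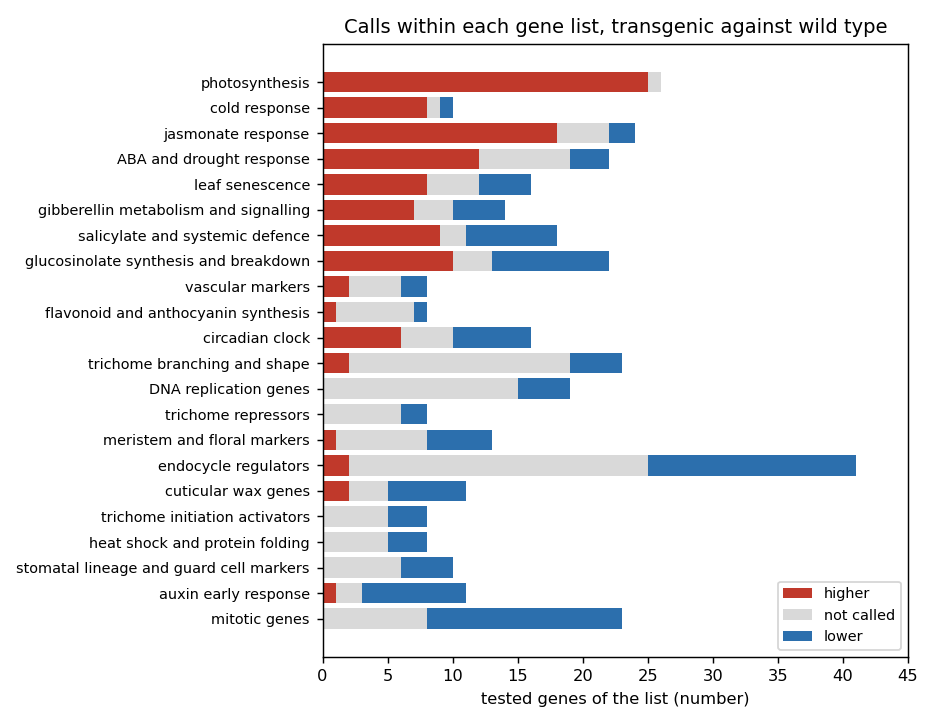
Number of tested genes (horizontal axis) called higher (red), not called (grey) or called lower (blue) in the transgenic lines, for each of the 22 gene lists with tested members. Photosynthesis has 25 of 26 genes higher and mitotic genes have 15 of 23 lower.

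In all, 11 of the 22 lists with enough tested members were called by camera with the preset correlation. With an estimated correlation camera called 0, and 5 had an unadjusted p under 0.05. The estimate itself was 0 for the mitotic list, -0.007 for the endocycle list and -0.011 for the heat shock list, not above the preset 0.01. A higher correlation between members is therefore not what ended the calls of these lists. For the mitotic list the unadjusted camera p was 3.33e-07 with the preset and 0.00493 with the estimate. The 2 forms of camera thus differ in more than the correlation, and a call lost with the estimate need not reflect correlated members. Fry, which does not compare a list with other genes, called 20.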

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

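Cyclic loess normalization and the 500-base minimum were chosen after seeing the data; all other settings were planned. Under every setting but a minimum 2-fold change (1278 genes, 717 higher and 561 lower), the count of changed genes stayed within 1.5 times 6949, and 5411 of them were also called after quantile normalization (5343 in the same direction) and 4735 after TPM (4583 in the same direction). Leaving out 1 sample gave 5889 to 6431 genes. Rescaling to TPM gave 1907 higher and 8363 lower genes by construction, since it divides each library by its total, and the totals differ between groups. The number of lists called, 11, became 7 at a mean of at least 5 FPKM, 5 after quantile normalization, 5 after rescaling to TPM, 0 with an estimated correlation and 20 with fry, which asks another question. The trichome initiation list kept a negative median but lost its call at a mean of at least 5 FPKM (-0.022, with fewer genes tested), with median-of-ratios factors (-0.52), quantile normalization (-0.28), TPM (-0.69), cyclic loess (-0.29) and an estimated correlation (adjusted p = 0.232), and its median ran from -0.69 to -0.36 over the samples left out. The endocycle list lost its call after quantile normalization (-0.066), TPM (-0.42) and with an estimated correlation (adjusted p = 0.0875), and the mitotic list with the last alone (adjusted p = 0.0875). The DNA replication list lost its call at 5 FPKM (-0.24), after quantile normalization (-0.12), TPM (-0.52) and cyclic loess (-0.13), and with an estimated correlation (adjusted p = 0.194). With fry the trichome repressors passed (adjusted p = 0.000492), and the glucosinolate list passed upward (adjusted p = 0.026) where camera's direction was down. Beyond those made by construction, the cause was not tested. Deviations from the group means of same-numbered samples correlated at -0.04, 0.05 and -0.02, against -0.07 to 0.09 for samples with different numbers. Expression thus gave no sign that the title numbers pair the samples, which does not show how they were handled. With the number as a replicate block 6706 genes (4155 higher, 2551 lower) and 11 lists were called. No named gene turned direction under any setting. Depth limits the low genes most, and transgenic line 3 held the fewest assigned fragments (0.90 of wild-type replicate 1). Of 10 splits of the 6 samples into 3 and 3, the real one gave 6949 genes and 11 lists and the highest other 0 genes and 6 lists (213 to 276 genes at an unadjusted p under 0.05, against 8290); in each case 1 split was as large, and 10 splits are too few for a share under 0.05.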

Other observations

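The gene families, the split of the glucosinolate list, the clock test, the 4 photosynthesis tests and the counts over other splits of the samples were chosen after the results were seen, while the tests of expression level and young tissue for the mitotic genes and of touch for the stress genes were written before their results. Families were taken by product name in the TAIR10.1 annotation, were picked after their members' values were seen and are given as counts and medians, untested. Percentiles compare a list's median with 10000 random lists matched on mean expression. The photosynthesis tests replaced a first version, written before its results and changed once they were seen. In it, cyclic loess met neither bound set for the trend with expression level (adjusted p = 0.0139, with 4.73e-22 to 0.188 over the alternatives). A match on length and expression among all genes, with 50 neighbours per member, put the list inside the central 95% (percentile 88.08, and 88.67 on expression alone), which would be read as fitting. Many of those neighbours were photosynthesis genes themselves, so these were removed and 20 neighbours taken to come closer in abundance. With 50 neighbours after the removal the percentiles were 98.07 on both properties and 99.06 on expression, so the reading of the match on both turns on that number.

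Of 47 small auxin-up RNA (SAUR) genes tested, 30 were lower and 5 higher (median log2 fold change -0.98). Growth-regulating factors, transcription factors of leaf growth, were lower in 6 of 8 and higher in 0 (median -0.66). Xyloglucan endotransglucosylase/hydrolases, which remodel the cell wall, were lower in 10 of 16 and higher in 2 (median -0.46), and arabinogalactan proteins lower in 12 of 24 and higher in 5 (median -0.54). Ovate family genes were lower in 5 of 11 (median -0.76) and ROTUNDIFOLIA-like peptide genes in 6 of 11 (median -0.77), each with 1 higher. All 6 medians stayed negative with size factors, quantile normalization, cyclic loess and TPM, while counts moved, as for the ovate genes with 3 lower after quantile normalization and 7 after TPM. Histone genes were lower in 17 of 85 and higher in 7 with the values as deposited (median -0.13), against 37 and 5 after quantile normalization, 38 and 5 after cyclic loess and 61 and 1 after TPM. The 342 ribosomal protein genes had 88 higher and 22 lower (median 0.07), but 19 and 148 after quantile normalization (median -0.19) and 15 and 221 after TPM (median -0.30), so the direction depends on the scaling.

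Cysteine-rich receptor-like kinases were higher in 14 of 26 with 1 lower (median 0.52), plant U-box ubiquitin ligases in 10 of 14 with 1 lower (median 0.67), MAP kinase kinase kinases in 7 of 13 with 0 lower (median 0.52) and disease resistance proteins in 28 of 64 with 5 lower (median 0.30). After TPM these counts were 12 higher and 5 lower (median 0.20), 7 and 4 (0.30), 6 and 3 (0.25), and 22 and 11 (0.00), in the same order. Within the glucosinolate list, the 6 genes of the indole branch, MYB34, MYB51, CYP79B2, CYP79B3, CYP83B1 and SOT16, rose, with a median log2 fold change of 0.75 and all 6 higher under every scaling tried. Of 12 genes of the aliphatic branch, 8 fell, among them MAM1, BCAT4, CYP79F1, CYP83A1, MYB28 and MYB29, and 2 rose (median -0.58), with 8 or more lower under every scaling tried. The difference between the branches was not itself tested. The chloroplast locus ATCG00080, named after its values were seen, was listed at 11488.9 FPKM in transgenic line 2 and at 0 in the other 5 libraries. Without this locus, FPKM of chloroplast-encoded genes summed to 168.8, 127.7 and 287.7 in wild type and 1140.1, 374.9 and 575.2 in the transgenic lines, with no overlap between groups.

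Photosynthesis genes were higher in the transgenic lines (25 of 26), while fold changes rose with expression level and the groups differed in FPKM totals. Each of these may make up part of the rise. The totals do not make up all of it: after rescaling to a common total 25 members were still higher, and the median went from 0.69 to 0.31. Rescaling leaves the trend with expression level in place, so it cannot decide on that trend. Against lists of genes unrelated to photosynthesis by name, the list's median lay at percentile 100 when matched on exonic length alone (genes 8.33 lower in log2 abundance) and 99.88 when matched on expression, where the matched genes still lay 1.07 lower. Of genes with a mean of at least 500, 1000 and 2000 FPKM, 73 of 76, 59 of 60 and 40 of 40 related to photosynthesis were higher (medians 0.67, 0.69 and 0.69) against 115 of 188, 27 of 55 and 7 of 19 others (medians 0.38, 0.13 and 0.07), which argues against the trend with level as the whole cause. Matched on length and expression at once the percentile was 97.23, inside the central 95%, among genes less abundant than the list, and in a test chosen after the results this cannot decide for or against a bias tied to both properties. Quantile normalization (median 0.05) and cyclic loess (median 0.09), both fitted at the top of the range to these same genes, took most of the rise away, and a difference in RNA selection or quality, in view of the higher chloroplast-encoded sums, and an effect of the genotype stay open and untested.

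Mitotic genes were lower in the transgenic lines (15 of 23) together with STM, KNAT1 and KNAT2. The trend of fold changes with expression level does not account for this, since the list's median lay at percentile 0.0 of lists matched on expression. A smaller share of young or meristematic tissue in the transgenic samples may account for part of the pattern: in a separate list of 17 young-tissue regulators, 10 were lower and 2 higher (13 and 0 after TPM; median -0.35, percentile 0.06), with the growth coactivator gene AN3 at 44.4 ± 1.82 and 27.0 ± 1.43 FPKM and the leaf polarity and patterning gene AS1 at 19.6 ± 1.37 and 10.2 ± 1.06 FPKM in wild type and transgenic lines. The members that rose, CLV1 (log2 fold change 0.42) and FIL (0.53), are not what a lower share alone would give. The labels state the same age for both groups and no leaf number, so leaf stage and an effect of the transgene on division are both left open. Whether a lower share of young tissue also bears on other falls was not tested and stays open. These include the trichome, endocycle, stomatal and auxin lists and the growth-regulating factors.

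In the drought, cold and jasmonate lists 12 of 22, 8 of 10 and 18 of 24 genes were higher and 3, 1 and 2 lower (7 and 7 after TPM in the drought list), and none of these lists was called with an estimated correlation. Whether a different time of harvest contributes is left open, since the fall of evening genes had been seen before the clock genes were split: 5 morning clock genes had a mean log2 fold change of 0.46 and 7 evening clock genes one of -0.62, a difference of 1.08, with CCA1 and PRR9 higher and ELF4 and LUX lower, although the evening gene GI rose by 0.46 and RVE1, counted with the morning genes, fell. Touch or handling before harvest may contribute, since 13 of 15 early touch and wound response genes were higher and 0 lower (2 lower after quantile normalization, cyclic loess or TPM; median 0.92, percentile 99.93), among them WRKY33 from 146.9 ± 7.26 to 419.1 ± 17.0 FPKM. The touch gene TCH3 rose by 1.12 on the log2 scale, while TCH2 and TCH4 had log2 fold changes of 0.08 and 0.00 and were not called. Both results could also come out this way if the transgene itself acts on the clock or on stress signalling. The labels give neither the hour of harvest nor its order, so these explanations and the genotype stay open. The protocol mentions drought treatments in identical words for all 6 samples. A difference in watering between the groups was not tested and stays open too.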
